A study of Mus musculus with 6 samples.

How the data were processed

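Chromatin accessibility was measured by ATAC-seq, in which a transposase inserts sequencing adapters into open DNA, in group 2 innate lymphoid cells (ILC2s) from mouse lung. The cells were sorted as lineage-negative, CD45-positive, RFP-positive cells after 4 days of injections of 500 ng of IL-33, an alarmin that activates ILC2s. Per the labels, each library pooled cells of several mice. WT mice carried Il5-Cre and intact Smarca4, and KO mice carried Il5-Cre and floxed Smarca4, the gene of Brg1, an ATPase of the BAF chromatin remodelling complexes. There were 3 libraries per genotype, of which replicates 1 and 2 came from females and replicate 3 from males.

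The authors deposited 2 tables of raw read counts per peak, 1 for the female libraries and 1 for all 6 libraries, each with its own set of peaks, and the values were whole numbers with a different total in each library. Per the submitters' processing notes, the tools were fastp, Bowtie2 2.5.3, MACS2, bedtools 2.31.1, ChIPseeker 1.28.3, deepTools 3.5.4 and edgeR 3.34.0, and the build was mm10. How each was set, whether reads were shifted for the transposase, how duplicate reads were handled and whether peaks were called on pooled libraries is not given in the sources used here. Coordinates are printed as the count tables give them, and whether their starts count from 0 or from 1 is not given there either.

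The table of both sexes held 66358 peaks with a median width of 942.5 bp, and that of the females held 57203 peaks with a median width of 1203 bp. Every column of values was mapped to a library by its name. Library totals in peaks ran from 4439571 to 9221244 counts in the table of both sexes and from 4465903 to 14560322 in the female table, so that KO replicates 2 and 3 of the first had the lowest precision per peak. The median count per peak was 25 to 49 in the table of both sexes. At the 6274 intervals that the tables share exactly, the column named WT replicate 1 in the female table held the same count as WT replicate 2 of the other table at 96.2% of intervals, and the column named KO replicate 1 the same as KO replicate 2 at 100%. The column named WT replicate 2 in the female table equalled WT replicate 1 of the other table at 0.61% of intervals, and that of KO replicate 2 equalled KO replicate 1 at 0.64%, so whether these columns hold the same libraries is not known. Names were kept as each table gives them. No pair of libraries within a group agreed within sampling noise, since the mean squared difference over that of counting alone was 2.92 or more in every pair, so no library appeared to be a copy of another. That each is a separate sample rests on the labels.

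The main test was edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) on the counts as deposited, with TMM scaling, the default filter on low counts and Benjamini-Hochberg adjustment, and a peak was called at an adjusted p under 0.05. Fold changes are KO minus WT on the log2 scale, and their standard error (SE) was taken from the fold change and the F statistic. All 6 libraries of the table of both sexes were fitted with sex as a covariate. The female table was fitted with genotype alone. Sex and the genotype-by-sex interaction were tested in the table of both sexes, where each genotype has 1 male library that is assumed to vary like the female ones. The p-values measure the spread between these pooled libraries. With groups of 3 libraries, an exact two-sided permutation test of a single value could not go below 0.1.

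The reference used here gave the start and end of each gene on GRCm38, the assembly that mm10 denotes, without strands, exons or sequence. Each peak was therefore assigned to the protein-coding or lncRNA gene whose span lay nearest, up to 100 kb, in place of the gene with the nearest transcription start that had been planned, and a peak within 1 kb of either end of a gene span stood in for a promoter peak. In the table of both sexes 65705 peaks, or 99.0%, received a gene. Whether a peak lies in an exon, an intron or an untranslated region could not be read from this reference. Motif enrichment and corrections for GC content and peak width, which need the sequence, were not run. Counts were summed over the peaks of each gene and tested in the same way. The 19 gene lists held 427 entries, of which 426 matched a gene. They were tested with camera (limma 3.58.1) at a preset correlation of 0.01 and again with an estimated correlation. With an estimated correlation camera uses the 3 residual degrees of freedom of the fit. Few lists could be called that way, so a call lost there says little about a list.

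The lists, the test of each comparison and the rule for named genes were fixed before the data were examined. The rule took every peak of Smarca4, the 6 called peaks with the largest fall and the 6 with the largest rise among those with a mean of at least 50 counts, a named gene and all KO libraries on one side of all WT libraries, up to 4 genes per list with the smallest adjusted p, and 10 genes of ILC2 biology in every case. Unnamed gene models and pseudogenes were skipped, and some genes that the rule takes are not reported here. Alternatives covered the scaling, the filter, the threshold, DESeq2 (1.42.0), the covariates, the gene assignment, a replicate term and leaving out each library in turn. When either male library is left out, the sex term takes up the other male. Both of these fits then estimate the KO effect from the female libraries alone, so they are not separate checks of single libraries. On simulated counts for the table of both sexes (58515 peaks), 38% of peaks changed 2-fold and 90% of those changed 4-fold were recovered, with 11 false calls among 133. For the female table (55626 peaks) these shares were 24% and 72%, with 10 false calls among 105. In the simulations of peaks, false calls were a larger share of all calls than the threshold on the adjusted p aims for. The real female libraries also split by replicate number, and genotype alone called 0 lower and 2 higher peaks there. The simulated shares for that table therefore cannot be taken as the recovery in its real fit by genotype alone. For gene sums (19405 genes) 82% of genes changed 2-fold were recovered, with 10 false calls among 182, and camera called 5 of 5 shifted and 0 of 15 unshifted lists.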

Results

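ATAC-seq counts were available for 6 libraries of lung ILC2s from IL-33-treated mice, 3 with intact Smarca4 (WT) and 3 with floxed Smarca4 (KO), all with Il5-Cre. In the table of both sexes, totals in peaks were 9221244, 8951662 and 6769648 counts in WT replicates 1 to 3 and 7314398, 4439571 and 4572624 in KO replicates 1 to 3. The female table held 9053662 and 14560322 counts in WT replicates 1 and 2 and 4465903 and 11455423 in KO replicates 1 and 2. Replicate 1 of each genotype in the female table matched replicate 2 in the other table, and each number below is the one its table gives. The series asks how loss of Brg1 alters the chromatin of activated ILC2s.

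Accessibility at the targeted gene was examined first. Summed over its peaks, Smarca4 (chromosome 9, 21616106 to 21704230, mm10) had 70.7, 74.6 and 71.9 CPM (counts scaled to the library total) in WT replicates 1 to 3 and 77.2, 81.9 and 82.3 CPM in KO replicates 1 to 3, a difference of 0.15 (log2, SE 0.10, adjusted p = 0.39, edgeR quasi-likelihood test). The peak at the start coordinate of the gene, 21615232 to 21617689, had 31.6 ± 2.54 CPM in WT and 37.6 ± 6.22 in KO (SD, n = 3, adjusted p = 0.358). The peak at 21609294 to 21610669 had 30.9 ± 2.34 CPM in WT and 30.5 ± 6.04 in KO, with an adjusted p of 0.945. The 3 weaker tested peaks, at 21625573, 21626488 and 21630749, had adjusted p of 0.843, 0.248 and 0.555, and the peaks at 21638432 and 21678765 were too shallow to test, with at most 10 counts in a library. Which part of the gene is floxed is not given in the sources used here, so these peaks do not check the genotype labels.

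More peaks were less accessible in KO than were more accessible. Of 58515 peaks tested in both sexes, 2820 were less accessible and 1006 more accessible in KO, so that 73.7% of called peaks were lower. The lower peaks had a median of 18.9 CPM in WT and 9.40 in KO, and the higher peaks 5.11 CPM in WT and 11.5 in KO. All KO libraries lay on one side of all WT libraries at 27.2% of all tested peaks, against 10% expected by chance. Lower peaks numbered 1174, 885 and 564 without WT replicates 1, 2 and 3 and 1593, 3536 and 647 without KO replicates 1, 2 and 3. Higher peaks numbered 297, 273 and 253 without WT replicates 1, 2 and 3 and 769, 1022 and 222 without KO replicates 1, 2 and 3. The fits without WT replicate 3 and without KO replicate 3 both rest on the females, whose libraries in this table alone gave 575 lower and 239 higher peaks. The split also moved with the scaling. Factors from peaks near gene ends gave 2836 lower and 582 higher peaks (83% lower), and factors from peaks away from gene ends, a setting added after the data were examined, gave 2347 lower and 1329 higher (63.8% lower).

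**Figure D1:**
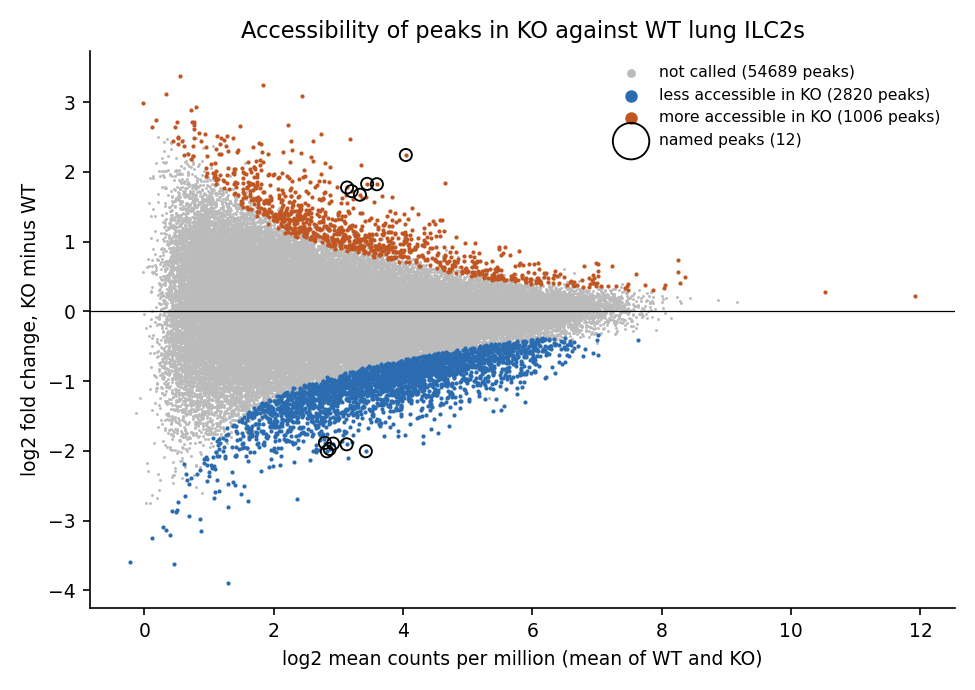
Each point is a peak of the table of both sexes, with its log2 mean CPM on the horizontal axis and its log2 fold change, KO minus WT, on the vertical axis. Blue and orange points are the 2820 lower and 1006 higher peaks called by edgeR, grey points were not called, and black rings mark the 12 peaks named in the text.

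The 6 named falls were close to 4-fold. Inside Rgs12, a regulator of G protein signalling (chromosome 5, 35037559 to 35038227), accessibility fell from 11.3 ± 1.30 to 2.85 ± 0.599 CPM (SD, n = 3, log2 −2.01, SE 0.31, adjusted p = 0.00147). A peak inside Adam12, a metalloprotease gene (chromosome 7, 134113918 to 134115096), fell from 16.7 ± 0.380 to 4.72 ± 3.88 CPM, with 9.20 CPM in the male KO library and 2.47 and 2.48 in the female ones. A peak inside Prr5l, which encodes a partner of the mTORC2 kinase complex (chromosome 2, 101816497 to 101817550), fell from 11.6 ± 1.14 to 2.95 ± 0.737 CPM. The other falls were at 139991359 to 139992524 on chromosome 4, 23333 bp from Klhdc7a (log2 −1.91, SE 0.29), at 69107767 to 69108726 on chromosome 15, 5973 bp from Khdrbs3, an RNA-binding protein gene (log2 −1.88, SE 0.31), and at 69818734 to 69819623 on chromosome 11, 247 bp from Spem2 (log2 −1.90, SE 0.33). The Spem2 peak was no longer called without WT replicate 3 (adjusted p = 0.0569).

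Among the named rises, a peak inside Car8, a carbonic anhydrase-related gene (chromosome 4, 8154983 to 8156853), rose from 5.77 ± 2.16 to 27.2 ± 7.94 CPM (SD, n = 3, log2 2.24, SE 0.28, adjusted p = 4.86e-04). A peak 11839 bp from Zc3h12c, of the Regnase family of RNases (chromosome 9, 52180569 to 52181764), rose from 4.96 ± 2.45 to 16.8 ± 3.30 CPM. A peak inside Nup210, a nuclear pore gene (chromosome 6, 91066666 to 91067762), rose from 5.51 ± 2.72 to 18.6 ± 2.02 CPM. The remaining rises lay 7871 bp from Emb, the gene of the adhesion protein embigin (chromosome 13, 117282286 to 117283192, log2 1.78, SE 0.28), inside Ncoa7 (chromosome 10, 30712435 to 30713225, log2 1.73, SE 0.27) and inside Inpp4b, a phosphoinositide phosphatase gene (chromosome 8, 81482435 to 81483468, log2 1.67, SE 0.30). Their adjusted p were between 0.00149 and 0.00355.

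**Figure D2:**
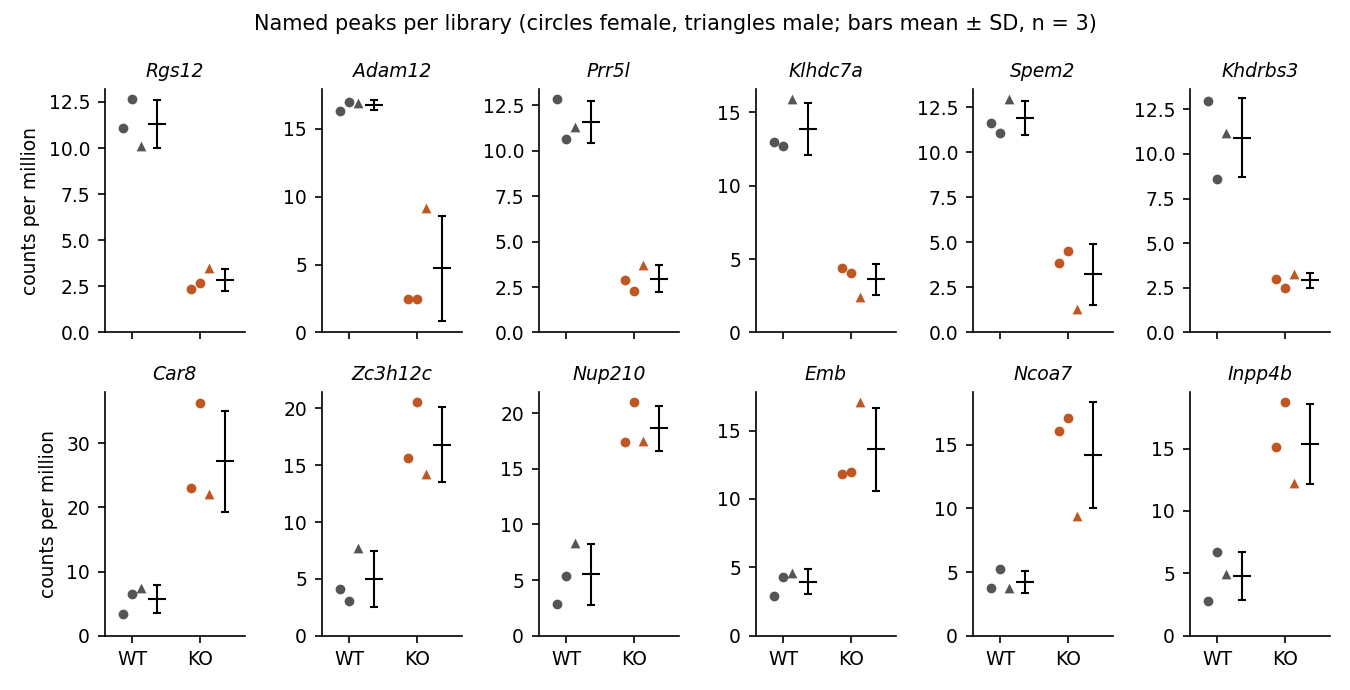
CPM of the 12 named peaks in each library, with circles for female and triangles for male libraries and bars for the mean ± SD of 3 libraries. At the 6 upper peaks every KO library lay below every WT library, and at the 6 lower ones above, as the rule that chose them required.

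Lower peaks were depleted near gene ends. Of the lower peaks 13.8% lay within 1 kb of an end of a gene span, against 30.5% of uncalled peaks (odds ratio 0.364, 95% interval 0.325 to 0.406, Fisher's exact test, p = 1.17e-91). For higher peaks the share was 24.1% (odds ratio 0.722, interval 0.622 to 0.837, Fisher's exact test, p = 7.86e-06). Peaks are not independent replicates, so these p-values describe this set of peaks. Over all tested peaks, the median log2 fold change was 0.061 at the 17304 near gene ends and −0.029 at the 41211 others. Peaks near gene ends held 53.5, 52.3 and 51.2% of counts in WT replicates 1 to 3 and 56.4, 52.6 and 54.3% in KO replicates 1 to 3. A library-wide difference of this kind could add to the depletion of lower peaks, and the odds ratios do not separate it from changes at single sites.

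With counts summed over the peaks of each gene, 1287 of 19405 genes tested fell in KO and 437 rose. The counts in each list below are to be read against these. Some genes of the ILC3 and type 17 programme lost accessibility in KO. Of 15 measured members 7 fell, 0 rose and 8 were not called over all genes tested, and 7 fell when adjusted over the list alone. Il17a, the type 17 cytokine gene, fell from 62.0 ± 11 to 32.5 ± 1.66 CPM (SD, n = 3, log2 −0.92, SE 0.13, adjusted p = 5.66e-04), with 3 of its 5 peaks called lower. Nrp1 fell by 0.55 (SE 0.10) and Il1r1, an IL-1 receptor gene, fell by 0.75 (SE 0.15) on the log2 scale. Among the members not called, Stat3 had 0.13 (log2, SE 0.10, adjusted p = 0.427), Ltb 0.12 (SE 0.10, adjusted p = 0.491) and Il17f −0.23 (SE 0.19, adjusted p = 0.487), all 3 named after their values were seen. Of the 15, 4 fell without WT replicate 2, WT replicate 3 or KO replicate 3, and with peaks near gene ends only 2 of 13 fell, with neither Nrp1 nor Il1r1 called. In the female table edgeR called 0 by genotype alone, with 7 lower and 0 higher at an unadjusted p under 0.05, and DESeq2 called 1 lower. With the replicate number as a term, Il17a, Nrp1 and Il1r1 were called lower there (adjusted p of at most 1.06e-05, edgeR). The list was lower than other genes with camera (adjusted p = 1.06e-05), a call lost with an estimated correlation (adjusted p = 0.39 with an estimated correlation).

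Some T cell markers and some ILC1 and NK cell genes fell as well. Of 12 measured T cell markers 3 fell and 0 rose over all genes tested, and 8 fell when adjusted over the list alone. The 3 were Ubash3a (log2 −0.67, SE 0.13), the costimulatory receptor gene Cd28 (log2 −0.98, SE 0.19) and the CD3 chain gene Cd3d (log2 −0.38, SE 0.12), while Cd5 had −0.99 (SE 0.33, adjusted p = 0.0731). Camera gave an adjusted p of 6.29e-04, and an adjusted p = 0.39 with an estimated correlation. Of 27 ILC1 and NK cell genes 3 fell and 0 rose, and 4 fell when adjusted over the list alone. The 3 were the granzyme gene Gzmb (log2 −0.92, SE 0.16), the receptor gene Klrk1 (log2 −1.01, SE 0.21) and the interferon gamma gene Ifng (log2 −0.50, SE 0.12). Il18r1 had −0.27 (SE 0.09, adjusted p = 0.0525). Camera gave an adjusted p of 0.0431 for this list, and an adjusted p = 0.407 with an estimated correlation. The T cell count fell to 0 without WT replicate 3 or KO replicate 3, fits that both rest on the females. Adjusted over the list alone it was 5, 3 and 3 without WT replicates 1, 2 and 3 and 4 and 3 without KO replicates 1 and 3. Of the ILC1 and NK genes 1 fell without WT replicate 3 or KO replicate 3, and 6 fell and 1 rose without KO replicate 2. Adjusted over that list alone, 2 fell without WT replicate 1, WT replicate 3 or KO replicate 3, and 7 fell and 1 rose without KO replicate 2. The camera call of the ILC1 and NK list was lost without WT replicate 1 (adjusted p = 0.0658), WT replicate 3 (0.0509), KO replicate 1 (0.181) and KO replicate 3 (0.0546). Cd28 and Ubash3a were not called without WT replicate 3 or KO replicate 3 (adjusted p of at most 0.0835 and 0.0587). Klrk1 was not called without WT replicate 2, WT replicate 3 or KO replicate 3 (at most 0.0740), nor Ifng without WT replicate 1, WT replicate 3 or KO replicate 3 (at most 0.120). The call of Cd3d was lost whichever of the 6 libraries was left out (at most 0.221).

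Some effector genes of ILC2s fell. Of 21 measured type 2 cytokines and effector products 7 fell, 0 rose and 14 were not called, with 7 falls also when adjusted over the list alone. The 7 falls were Il2 (41.8 ± 7.03 to 21.8 ± 5.11 CPM, SD, n = 3, log2 −0.96, SE 0.16, adjusted p = 0.00146), the chemokine gene Ccl1 (log2 −0.55, SE 0.09), the arginase gene Arg1 (log2 −0.72, SE 0.14), Calca (log2 −0.52, SE 0.14), Areg, the gene of the tissue repair factor amphiregulin (log2 −0.38, SE 0.11), and, named after their values were seen, the type 2 cytokine gene Il9 (115 ± 8.03 to 91.4 ± 9.48 CPM, log2 −0.34, SE 0.10, adjusted p = 0.036, 0 of 3 peaks called) and the chemokine gene Ccl17 (log2 −0.48, SE 0.13). Other cytokine genes were not called. Il5 had 130 ± 10.4 CPM in WT and 142 ± 8.01 in KO (adjusted p = 0.466), Il13 205 ± 10.8 and 222 ± 7.82 (adjusted p = 0.456), Il4 49.95 ± 11.4 and 42.0 ± 12.4 (adjusted p = 0.30) and Csf2 36.9 ± 5.01 and 42.4 ± 2.23 (adjusted p = 0.394), with 0 called peaks at each. All mice carried Il5-Cre and the cells were sorted as RFP-positive. If RFP follows Il5-Cre, the sort favours cells with an active Il5 locus in both genotypes, which limits what the Il5 value shows. Camera called the list lower (adjusted p = 0.0249), but not with an estimated correlation (adjusted p = 0.39 with an estimated correlation), nor without WT replicate 3 (adjusted p = 0.0620), KO replicate 1 (0.0824) or KO replicate 3 (0.0644). Areg was not called without WT replicate 1, WT replicate 3, KO replicate 1 or KO replicate 3 (adjusted p of at most 0.334), Calca when any 1 library but KO replicate 1 was left out (at most 0.142), Il9 and Ccl17 when any 1 library but KO replicate 2 was (at most 0.178 and 0.184), and Arg1 without WT replicate 3 or KO replicate 3 (at most 0.0730). The falls numbered 3, 4 and 2 without WT replicates 1, 2 and 3 and 4 and 2 without KO replicates 1 and 3. They numbered 3 without a sex covariate, and with peaks near gene ends only 2 of 19 fell and 1 rose.

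Across the locus that holds Il4, Il13, Rad50 and Il5, from 53582460 to 53755103 on chromosome 11, a region chosen after its values were seen, 0 of 25 tested peaks were called by edgeR and 0 by DESeq2. At an unadjusted p under 0.05 there were 8, of which 5 were lower in KO. Over all 58515 peaks tested, 13727 had such a p, of which 8121 were lower. The smallest adjusted p was 0.0570, at 53691732 to 53692368 inside Rad50 (5.73 ± 1.84 CPM in WT, 2.61 ± 1.54 in KO, SD, n = 3, edgeR). The limit of the sort given for Il5 may hold for this locus too.

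**Figure D3:**
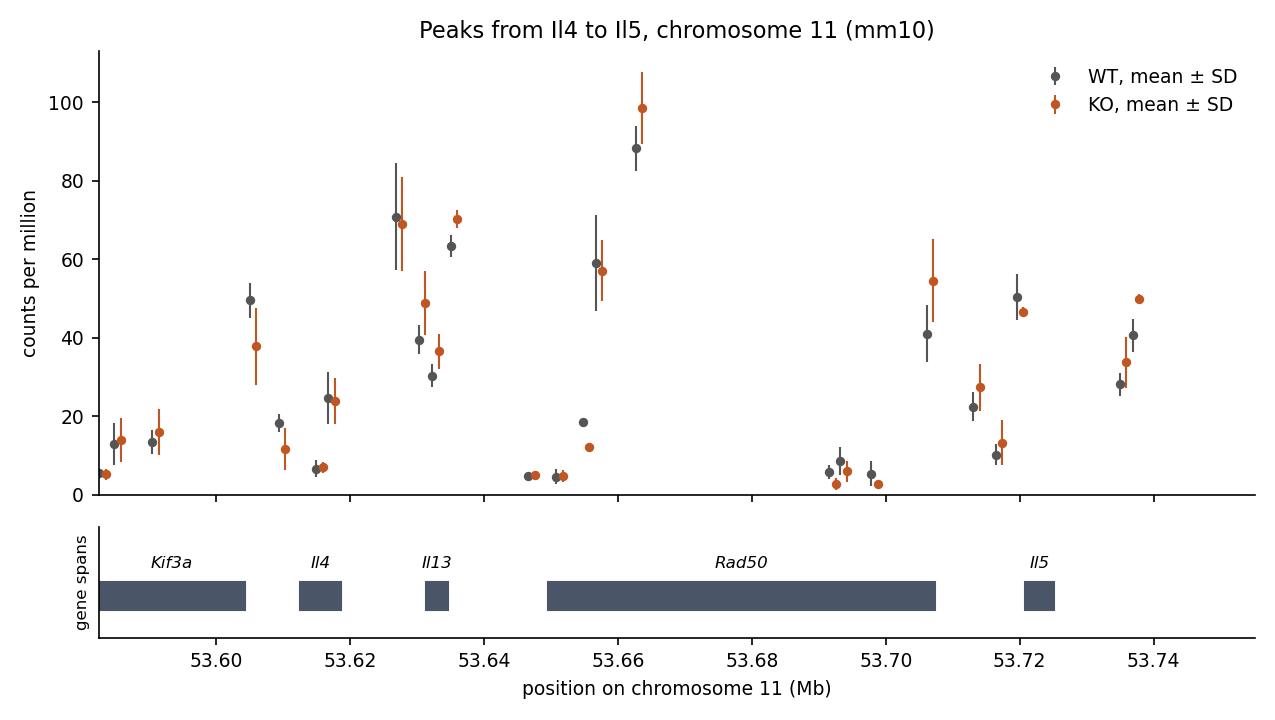
CPM of the 25 tested peaks from Il4 to Il5 against position on chromosome 11 (mm10, Mb), as mean ± SD of 3 WT (grey) and 3 KO (orange) libraries drawn slightly apart, with gene spans below. The strongest peak, inside Rad50, had 88.2 ± 5.72 CPM in WT and 98.5 ± 9.22 in KO.

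Of 27 measured receptor genes of ILC2s 4 fell and 1 rose over all genes tested, and 10 fell and 2 rose when adjusted over the list alone. These counts moved when libraries were left out. Over all genes tested 8 fell and 1 rose without KO replicate 2, 3 fell and 3 rose without KO replicate 1, 5 fell and 0 rose without WT replicate 1, and 3 fell and 0 rose without WT replicate 2, WT replicate 3 or KO replicate 3. Adjusted over the list alone, 4 fell and 0 rose without WT replicate 2, 4 fell and 1 rose without WT replicate 3 or KO replicate 3, and 8 fell and 5 rose without KO replicate 1. With peaks near gene ends only, 2 of 23 fell and 0 rose. Vipr2, a receptor for vasoactive intestinal peptide, fell from 264 ± 11.7 to 165 ± 21.1 CPM (SD, n = 3, log2 −0.68, SE 0.10, adjusted p = 6.29e-04), with 6 of 11 peaks lower. The IL-10 receptor gene Il10ra fell by 0.59 (SE 0.11), the prostacyclin receptor gene Ptgir by 0.55 (SE 0.11) and Kit, named after its value was seen, by 0.38 (SE 0.10) on the log2 scale. Kit was not called without WT replicates 2 or 3 or KO replicates 1 or 3 (adjusted p of at most 0.209). Il2ra, the high-affinity IL-2 receptor chain, rose from 333 ± 10.3 to 416 ± 43.7 CPM (log2 0.32, SE 0.08, adjusted p = 0.0247), with 4 of 18 peaks higher, and was not called without WT replicates 1, 2 or 3 or KO replicate 3 (adjusted p of at most 0.152). Il1rl1, the IL-33 receptor gene, had 385 ± 63.3 CPM in WT and 430 ± 82.8 in KO (adjusted p = 0.432, 1 of 15 peaks higher), Klrg1 had 356 ± 43.3 and 400 ± 84.6 (adjusted p = 0.345, 1 of 11 peaks higher), and Il7r had 165 ± 23.6 and 178 ± 19.7 (adjusted p = 0.568, 0 of 6 peaks called). Camera gave an adjusted p of 0.0576 for the list (adjusted p = 0.591 with an estimated correlation), and with the preset correlation called it lower without WT replicate 1 (adjusted p = 0.0266) or KO replicate 2 (0.00568).

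Of 28 ILC2 transcription factor genes 2 fell and 0 rose, and 1 fell when adjusted over the list alone. A share of 2 in 28 is close to that over all genes tested, where 1287 of 19405 fell. The 2 were Runx3 (log2 −0.32, SE 0.08, adjusted p = 0.0222) and Runx1 (log2 −0.24, SE 0.07, adjusted p = 0.0471), both not called when any 1 library but KO replicate 2 was left out, with adjusted p of at most 0.128 and 0.207. Without KO replicate 2 there were 5 falls, or 6 when adjusted over the list alone. Loess offsets gave 0 falls and 2 rises, total counts 1 and 2, and peaks near gene ends only 0 and 0. Gata3, the lineage-defining factor, had 345 ± 24.5 CPM in WT and 340 ± 25.2 in KO (SD, n = 3, adjusted p = 0.913), with 0 of 14 peaks called. Rora had 1840 ± 21.5 and 1792 ± 134 CPM (adjusted p = 0.784), with 4 of 70 peaks lower and 1 higher. Klf6 (log2 0.26, SE 0.08) and Bcl11b (log2 −0.24, SE 0.08) had adjusted p of 0.0624 and 0.0758. Among 20 inhibitory receptor and NR4A genes only Btla was called, here and when adjusted over the list alone, falling from 86.2 ± 19.3 to 42.3 ± 14.6 CPM (log2 −1.07, SE 0.16, adjusted p = 6.50e-04), while Lag3, Cd244a and Pdcd1 had adjusted p of 0.0866, 0.131 and 0.144. Without KO replicate 2, 3 members fell, or 5 fell and 1 rose when adjusted over the list alone. Without KO replicate 1, 1 member fell and 1 rose in both ways of adjustment, and 2 fell over the list alone without WT replicate 3 or KO replicate 3. Camera called that list lower (adjusted p = 0.0384), not with an estimated correlation (adjusted p = 0.43 with an estimated correlation) and not without WT replicate 3 (adjusted p = 0.0509), KO replicate 1 (0.226) or KO replicate 3 (0.0546). Camera gave the transcription factor list an adjusted p of 0.851.

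**Figure D4:**
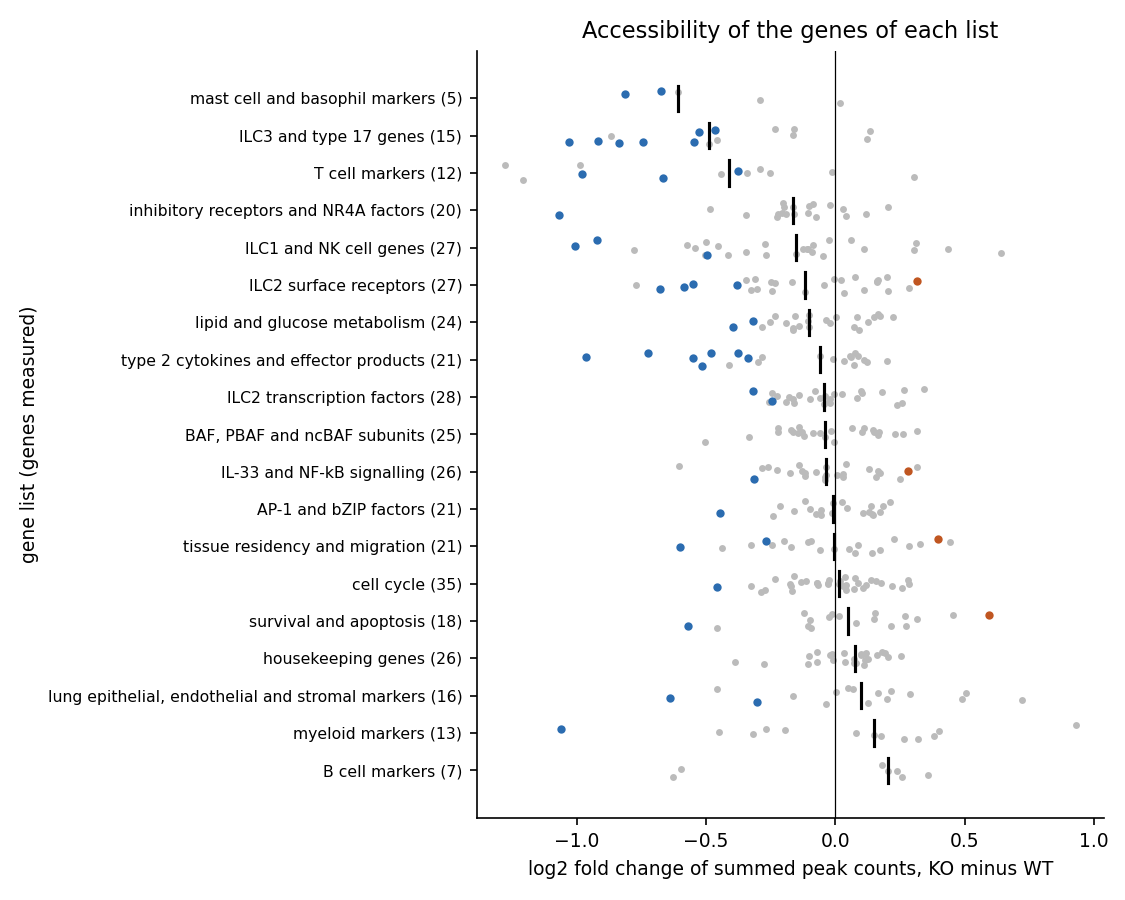
Each point is a gene, with its log2 fold change of counts summed over its peaks, KO minus WT, on the horizontal axis and its list on the vertical axis, where the number of genes measured is in parentheses. Blue points fell and orange points rose at an adjusted p under 0.05, grey points were not called, and black bars mark list medians, which were −0.49 for the ILC3 and type 17 genes and 0.08 for the housekeeping genes.

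Migration and residency genes included 2 falls and 1 rise among 21, or 3 and 3 when adjusted over the list alone. Itgae, the gene of the CD103 integrin chain, fell by 0.60 (SE 0.11, adjusted p = 0.00301), Cxcr4 fell by 0.27 (SE 0.08) and Ccr7, a lymph node homing receptor gene, rose by 0.40 (SE 0.10, adjusted p = 0.0157) on the log2 scale, while Ccr4 had 0.28 (SE 0.09, adjusted p = 0.0584). Among 26 IL-33 and NF-kB signalling genes Map3k8 fell (log2 −0.31, SE 0.09) and Tnfaip3, which encodes the NF-kB inhibitor A20, rose (log2 0.28, SE 0.08), in both ways of adjustment, and Rela and Irak2 had adjusted p of 0.0713 and 0.0751. Among 18 survival genes the death receptor gene Tnfrsf10b fell (log2 −0.57, SE 0.10, adjusted p = 0.00152) and Bcl2a1b rose (log2 0.60, SE 0.17), or 2 fell and 1 rose when adjusted over the list alone, with Fas at an adjusted p of 0.0502 and Casp8 at 0.121. Bcl2a1b belongs to a family of near-identical copies, so its reads are uncertain. Among 24 lipid and glucose genes Dgat2 (log2 −0.40, SE 0.10) and the glucose transporter gene Slc2a1 (log2 −0.32, SE 0.10) fell, in both ways of adjustment, and Ldha and Pkm had adjusted p of 0.0782 and 0.139. Of 21 AP-1 and bZIP genes Jdp2 fell (log2 −0.45, SE 0.08, adjusted p = 0.00318) in both ways of adjustment, with Fosb, Bach1 and Mafg at adjusted p of 0.0888, 0.151 and 0.196. Of 35 cell cycle genes Birc5 fell (log2 −0.46, SE 0.13, adjusted p = 0.0365), but 0 fell when adjusted over the list alone, and Cdc20, Cdkn2a and E2f2 were not called. With peaks near gene ends only Map3k8 had 0.03, and with the gene of the nearest span end Slc2a1 had 0.15. The call of Tnfrsf10b held without each library in turn. Without KO replicate 2 there were 5 falls and 1 rise among migration genes, 1 and 2 among NF-kB genes and 3 and 0 among lipid and glucose genes, and without KO replicate 1 there were 2 and 0 among survival genes. The balance also moved with the scaling. Total counts gave 1 fall and 3 rises among migration genes and 0 and 2 among NF-kB genes. Loess offsets gave 1 and 4 among the former and 0 and 2 among the latter. Without both libraries numbered 1 there were 2 and 4, and 2 and 3. Itgae and Jdp2 were not called without WT replicate 3 or KO replicate 3 (adjusted p of at most 0.0572 and 0.0628). Ccr7, Cxcr4, Map3k8, Tnfaip3 and Dgat2 were not called when any 1 library but KO replicate 2 was left out (at most 0.282), Slc2a1 when any but KO replicate 1 was (at most 0.320), Birc5 without WT replicates 2 or 3 or KO replicates 1 or 3 (at most 0.236) and Bcl2a1b without WT or KO replicates 1 or 2 (at most 0.187). Camera called none of these 6 lists (adjusted p of 0.69 or more). Over all genes tested 1287 of 19405 fell and 437 rose, so 1 or 2 falls in a list of this size are not particular to it. The AP-1 and residency lists had medians of −0.01 and 0.00 and means of −0.01 and −0.01 but an upward camera direction, and the cell cycle list a median of 0.01, a mean of −0.02 and a downward one.

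Of 25 BAF complex genes 0 were called by edgeR, 2 had an unadjusted p under 0.05 and 0 were called by DESeq2, and the smallest adjusted p were those of Arid2, Dpf1, Smarce1 and Smarca2, from 0.139 to 0.265. Of 26 housekeeping genes 0 were called, 3 had an unadjusted p under 0.05 and 0 were called by DESeq2, and Reep5, Snrpd3 and Polr2a had adjusted p of 0.134 to 0.259. Without KO replicate 1, 1 housekeeping gene rose. Camera gave these lists adjusted p of 0.996 and 0.608.

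Markers of other cell types were measured because the sort could hold other cells. Of 5 mast cell and basophil markers Cpa3 (log2 −0.81, SE 0.23, adjusted p = 0.0348) and Cma1 (log2 −0.67, SE 0.20, adjusted p = 0.0411) fell, in both ways of adjustment, and Hdc and Ms4a2 had adjusted p of 0.199 and 0.226. Of 16 lung structural markers Pdgfrb (log2 −0.64, SE 0.16) and Pecam1 (log2 −0.30, SE 0.09) fell, in both ways of adjustment, while Scgb1a1 and Foxj1 had values of 0.51 and 0.29 and were not called. Of 13 myeloid markers Itgax fell (log2 −1.06, SE 0.31, adjusted p = 0.0390), or 2 fell and 1 rose when adjusted over the list alone, and Itgam, Mrc1 and Flt3 had adjusted p of 0.0514, 0.0766 and 0.189. Of 7 B cell markers 0 were called by edgeR, 2 had an unadjusted p under 0.05 and 0 were called by DESeq2, with Blk, Cd79b, Pax5 and Cr2 at adjusted p of 0.126 to 0.341. Without KO replicate 1, 1 B cell marker fell, and without WT replicate 1, 1 myeloid marker rose and 0 fell. Cma1 and Pdgfrb were not called when any 1 library but KO replicate 2 was left out, and Pecam1 and Itgax when any but KO replicate 1 was (adjusted p of at most 0.291). Cpa3 was not called without WT replicates 2 or 3 or KO replicates 1 or 3 (at most 0.207). Camera gave adjusted p of 0.0559 for the mast cell (adjusted p = 0.544 with an estimated correlation), 0.996 for the structural, 0.996 for the myeloid and 0.994 for the B cell list, and with the preset correlation called the mast cell list lower without WT replicate 1 (adjusted p = 0.0432) or KO replicate 2 (0.00568).

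In the female table, which has 2 libraries per genotype, genotype alone gave 0 lower and 2 higher peaks of 55626 tested by edgeR. At an unadjusted p under 0.05 there were 4834 lower and 3865 higher, and DESeq2 called 348 lower and 220 higher. Of 379 members of the 19 lists 0 were called there by edgeR, 46 were lower and 13 higher at an unadjusted p under 0.05, and DESeq2 called 7 lower and 0 higher. The 2 higher peaks lay inside the gene model Gm32590 (chromosome 8, 127799647 to 127801108, log2 3.16, SE 0.36) and 31346 bp from Gm31641 (chromosome 16, 95150432 to 95153191, log2 2.29, SE 0.25), both with an adjusted p of 0.035 and named after their values were seen. The libraries also split by replicate number. At 24612607 to 24613220 on chromosome 1, replicate 1 had 5 counts in WT and 19 in KO and replicate 2 had 12829 and 12241, and at 98666239 to 98667329 on chromosome 2, replicate 1 had 120 and 66 and replicate 2 had 7788 and 7166. With the replicate number as a term, 5043 peaks were lower and 3804 higher, and each replicate alone holds too few libraries for a test. Of 19157 gene sums, 1835 were lower and 996 higher with that term, against 1 and 2 by genotype alone. Il17a, Vipr2 and Btla were then called lower (adjusted p of at most 1.06e-05, edgeR), while Areg was not (0.17). The absence of called list members by genotype alone therefore depends on leaving that term out. By genotype alone, edgeR called 0 peaks without WT replicate 1 and 0 without WT replicate 2. Without KO replicate 1 there were 838 lower and 380 higher calls, and without KO replicate 2 there were 489 and 429.

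Of the 2820 lower peaks of both sexes, 2708 had a female peak with a reciprocal overlap of at least 50%, and 100% of these had a negative fold change there, with medians of −1 and −0.95. For higher peaks 904 of 1006 matched and 100% had a positive fold change, with medians of 1.10 and 1.20. The tables share libraries, so this match is not independent evidence. In the table of both sexes, the libraries numbered 1 were those closest to replicate 2 of the female table (Pearson's r of log2 counts across shared intervals, which are not independent replicates, 0.980 in WT and 0.976 in KO). Without both of them, a fit added after the data were examined, 2335 peaks were lower and 1263 higher, while the camera calls of the type 2 cytokine (adjusted p = 0.0667), ILC1 and NK (0.190) and inhibitory receptor (0.190) lists were lost.

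The sexes differed at 85 of 61981 peaks, 38 of them on the X chromosome and all 38 less accessible in males. Firre, a long noncoding RNA gene tied to the inactive X (chromosome X, 50563120 to 50635321), had 17 of 19 peaks lower in males, with 174 and 96 counts in male WT and KO against 1690 to 4088 in the females. Xist, the RNA that silences the inactive X (chromosome X, 103460373 to 103483233), had 3 of 4 peaks lower, with 93 and 45 counts in males and 330 to 684 in females. Kdm6a and Kdm5c had 1 lower peak each. These genes were chosen after their values were seen. Another 3 called peaks had coordinates on the Y chromosome and were lower in males, with 6 to 170 counts against 50 to 589 in females, which carry no Y chromosome. Of the peaks called on the Y chromosome 0 were higher in males, so they do not check the sex labels. Autosomal peaks differed too, 22 lower and 22 higher in males. The interval 98666651 to 98667311 on chromosome 2 had 2415 and 2020 counts in males against 52 to 132 in females of this table, but replicate 2 of the female table had 7788 and 7166 counts at the overlapping interval given above, so the difference there did not follow sex. The interval 109011646 to 109012118 on chromosome 11 had 1 and 0 counts in males against 358 to 622 in females of this table. In the female table the overlapping interval had 622 and 358 counts in WT and KO of one replicate number but 58 and 77 in replicate 2, so that difference did not follow sex alone. The autosomal calls therefore cannot be read as effects of sex alone. Whether males and females were processed apart is not given in the sources used here.

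The KO effect differed between the sexes at 1 of 58515 peaks. At 101626777 to 101628459 on chromosome 11, at Rdm1, a gene of DNA repair, the female libraries had 46.5 and 53.7 CPM in WT and 80.3 and 67.6 in KO, while the males had 36.9 in WT and 7.83 in KO (interaction log2 −2.80, SE 0.35, adjusted p = 0.0323, edgeR). An unadjusted p under 0.05 was reached by 1288 peaks, and DESeq2 called 1 peak. Each genotype has 1 male library, so the difference rests on a single KO male.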

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

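The setting with factors from peaks away from gene ends, and the tests of sort purity, of T cells among the sorted cells and of depth and a technical batch in the female table were chosen only after the results they bear on were seen.

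The peak at Rdm1 on chromosome 11 stood out because the KO effect differed between the sexes, with a genotype-by-sex interaction of −2.80 (log2, male minus female, SE 0.35, adjusted p = 0.0323, edgeR). It rests on 1 KO male library with 7.83 CPM, and no explanation was tested.

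More peaks were lower than higher in KO, 73.7% of those called. After every library was thinned to the smallest total the share was 73.2%. The lower of the shares with loess offsets and with factors from peaks near gene ends was 69.5%. Within this set of peaks, these shares argue against depth or an abundance trend as the whole cause. Thinning leaves the set of peaks as it was, so whether depth decided which peaks entered it was not tested. The share was 63.8% with factors from peaks away from gene ends (2347 lower, 1329 higher) and 64.4% with both factors and tests on such peaks alone, between the bounds set in advance (55% and 65%). A scaling factor of that kind and a weaker signal at such peaks throughout the KO libraries therefore stay open beside an effect of Smarca4 loss on single sites. Of the 10 splits of the 6 libraries, 1, the real one, called as many peaks (3826, highest other 1) and 1 as many genes (1724, highest other 0), and 10 splits are too few for a share under 0.05.

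The ILC3 and T cell lists were lower in KO with camera's preset correlation, but not with an estimated one (adjusted p = 0.39 for both with an estimated correlation). The estimated setting left camera 3 degrees of freedom, so it does not decide whether the lists fell. T cell markers (mean −0.54, SD 0.49, 12 genes) lay below B cell, myeloid and lung structural markers (mean 0.05, SD 0.41, 36 genes), which did not fall as a set. The two-sided permutation p was 1.50e-04. It was 8.20e-04 with the 5 mast cell and basophil markers added to the others, which themselves had a mean of −0.47 (SD 0.33). These p-values treat genes as independent, and the T cell list was tested because it had already been seen to be lower. Other cell types need not be equally frequent in the WT sort, so this comparison cannot decide whether that sort was less pure in general. T cells, or T cells together with mast cells or basophils, may have been more frequent in the WT sort, although the lineage gate would remove T cells. Of 12 T cell markers, 2 (Trat1 and Themis) had a 95% interval above the list median of −0.41, while the most accessible, Cd247, had 183 CPM in WT and 154 in KO. That count used the 18.1 degrees of freedom of the edgeR test, a choice made after 3 residual degrees of freedom had given 0, so such cells and a change within ILC2s cannot be told apart.

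The female table gave far more calls with a replicate term (8847) than without (2). After its libraries were thinned to the same total, 5987 peaks were still called with the term and 1 without, which argues against a difference in depth between replicates as the whole cause. Of 16 peaks at least 8-fold apart between replicates in both genotypes, 15 went the same way, but the split had been seen at some of these peaks before and neighbouring peaks are not independent. A technical batch shared by libraries with the same number therefore stays open, the labels name none, and a biological difference between the pools of mice was not tested.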

How the results depend on the processing

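The robust prior, thinning, the nearest span end, protein-coding genes, leaving out both libraries numbered 1, factors from peaks away from gene ends, DESeq2 on gene sums of the female table and list-only adjustment without each library were chosen after the data were examined. Of 240 alternative values of the 12 named peaks 238 kept their direction and side of the threshold. These peaks had been chosen as the largest called changes with separated libraries, so much of this stability follows from the choice. All 240 values come from the table of both sexes. In the female table edgeR called 2 peaks by genotype alone, and neither was a named peak. Of 1279 values of named genes 955 counted as the same, 208 lost a call, 53 gained one and 61 moved otherwise. For uncalled genes the same means still uncalled and within 1 SE, whatever the sign, as for Gata3 (−0.02, and 0.056 in the female table). Of called genes 2 values reversed: Map3k8 with peaks near gene ends only (0.027) and Slc2a1 with the gene of the nearest span end (0.15). Smaller counts with a stricter threshold follow from its construction. Fewer libraries did not always give smaller counts. Without KO replicate 2, 3536 peaks were lower and 1022 higher, against 2820 and 1006 with all libraries. The cause of the changes other than the threshold was not tested. Low depth, as in KO replicates 2 and 3, limits calls at weak peaks.

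For both sexes, lower and higher peaks numbered 2080 and 622 with DESeq2, 2836 and 582 with factors from peaks near gene ends, 2347 and 1329 with factors from peaks away from them, 1680 and 588 with a stricter filter, 1441 and 632 with a 2-fold threshold, 575 and 239 in the females of that table, and 564 to 3536 and 222 to 1022 without each library in turn. With the replicate number as a block they were 5641 and 2964. Of gene sums 2351 were lower and 1229 higher with the block, against 1287 and 437 without. Il18r1, Rela and Lag3 were then called (adjusted p of at most 0.00819, edgeR), while Il5, Il13 and Gata3 were not (at least 0.29). Same-numbered WT and KO libraries had deviations correlated at 0.318, 0.0968 and 0.184, against −0.237 to 0.0559 for other pairs. The numbers were not taken to pair libraries in the main fit. Each library correlated best with its own number, so a pairing stays open.

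For females, lower and higher peaks numbered 348 and 220 with DESeq2, 1 and 7 with loess offsets, 1 and 4 with factors from peaks near gene ends, 1 and 7 with no filter, 0 and 0 with a stricter filter, 1 and 5 on autosomes, 0 and 4 with a robust prior, 0 and 1 after thinning, 5043 and 3804 with the replicate block, and 0 to 838 and 0 to 429 without each library. Peaks differing between sexes numbered 34 on autosomes tested alone.

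The number of lists called lower, 5 at first, was 2 with loess offsets, in the female table, without a sex covariate and without both libraries numbered 1, 3 with peaks near gene ends only, 8 with protein-coding genes only, 0 with an estimated correlation, and 2 to 7 without each library. Adjusted p with loess offsets were 0.0697 (ILC1 and NK), 0.272 (inhibitory) and 0.0809 (type 2). In the female table they were 0.0693, 0.109 and 0.138, without a sex covariate 0.0505 for all 3, and without both libraries numbered 1 0.190, 0.190 and 0.0667. Peaks near gene ends only gave 0.159 (inhibitory) and 0.599 (type 2), and the nearest span end 0.0994 (inhibitory). With an estimated correlation they were 0.407 (ILC1 and NK), 0.430 (inhibitory) and 0.390 (ILC3, T cell and type 2). The estimate was 0.01 for the ILC1 and NK list, equal to the preset, and −0.014 for the type 2 list. Their unadjusted camera p still rose, from 0.0113 to 0.0858 and from 0.00393 to 0.0509. These losses therefore do not come from a higher correlation between genes. Calls were gained for mast cell markers with total counts (0.0461), the replicate block (0.0314) and protein-coding genes (0.0272), for receptors with the replicate block (0.0371), the nearest span end (0.0212) and protein-coding genes (0.00450), and for ILC2 transcription factors with protein-coding genes (0.0271). Without each library in turn the adjusted p ran from 0.0208 to 0.181 (ILC1 and NK), 0.00449 to 0.226 (inhibitory), 0.00449 to 0.0824 (type 2), 0.00568 to 0.540 (receptors) and 0.00568 to 0.361 (mast cell).

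Motif enrichment, corrections for GC content and width, alone or with the replicate block, and the share of gene ends among female calls were not run.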

Other observations

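All genes and tests in this part were chosen only after the results were seen.

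Called peaks gathered at some genes. Given 4.82% of tested peaks lower and 1.72% higher, 11 genes held more lower peaks than expected and 4 more higher ones (hypergeometric test, Benjamini-Hochberg adjusted over 19342 genes). Lower peaks gathered at Mical3 (8 of 15 peaks, adjusted p = 0.00264), at Vipr2 (6 of 11, 0.0174), at Nfatc2, which encodes a calcium-regulated transcription factor (7 of 17, 0.0192), at Prr5l (6 of 12, 0.0192) and at Itpr1, a calcium channel gene (11 of 50, 0.0404). Higher peaks gathered at Emb (6 of 26, 0.0371), Slc24a1 (4 of 8, 0.0371) and Aebp2, a partner of Polycomb complex 2 (5 of 17, 0.0375). Neighbouring peaks are not independent, so these p-values are too small where peaks of a gene move together. Both lower and higher peaks were present at 89 genes.

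In WT replicate 1 of the table of both sexes, the median deviation of chromosome 11 peaks was −0.07 (log2), and no other chromosome of that library lay below −0.02. The value was −0.07 in WT replicate 2 of the female table, where no other chromosome lay below −0.02.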
